A study of Homo sapiens with 8 samples.

How the data were processed

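RNA sequencing measured gene expression in cultured human cervical stromal cells, which had been derived from explants of cervical stroma and grown at 37 C in DMEM medium with 10% fetal bovine serum. The cells received prostaglandin E2 (PGE2) at 100 nM or the solvent dimethyl sulfoxide (DMSO) for 1 h or 24 h, with 2 libraries in each of the 4 groups. The labels number the libraries of a group 1 and 2 and do not say whether a number stands for a donor, a culture or a repeat of the library preparation. The p-values therefore measure only the spread between these libraries, which can be technical.

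The deposited values are raw counts per gene symbol for 19410 genes, described by the authors as known coding genes, in 1 table for the 8 libraries. The authors' notes name CASAVA 1.8.2, TopHat2 2.0.10, featureCounts, Subread 1.4.6, edgeR and genome build hg19, without stating the annotation release, the strand setting or any filter. Every column held whole numbers with a different total, and 3282 genes had 0 counts in every library. Gene names, exon overlaps, transcript length and GC content came from an annotation for a later build and were joined to the counts by name, and 95.2% of the tested genes had a length and a GC content.

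The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 13073, and library sizes were scaled with TMM factors. A quasi-likelihood model with robust dispersions and a mean per group was fitted to the 8 libraries at once, so the groups shared 1 estimate of the spread with 4 residual degrees of freedom. The spread between the 2 libraries of a group was unequal. Its chi-square per degree of freedom was 3.96 for DMSO and 15.7 for PGE2 at 1 h, and 20.7 for DMSO and 6.49 for PGE2 at 24 h. The comparisons were PGE2 against DMSO at 1 h and at 24 h, the difference between these effects (the effect at 24 h minus that at 1 h), and DMSO at 24 h against DMSO at 1 h. F-tests were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors after ± are standard errors for log2 fold changes, taken as the estimate over the square root of its F statistic, and standard deviations for CPM, which are counts scaled to a common library size with the TMM factors (n = 2).

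A rule fixed the genes to name. For each PGE2 comparison these were the 10 with the largest positive and the 10 with the most negative log2 fold change among genes past the threshold, with an average log2 CPM of at least 1 and both treated libraries on the same side of both controls. For the other comparisons it took 5 in each direction, for the difference between the times without the condition on libraries. The rule also named PTGER1, PTGER2, PTGER3, PTGER4, PTGS2 and HPGD in both PGE2 comparisons, and up to 4 members with the smallest p of each of 22 gene lists. Some genes of these lists are not reported here. The lists held 389 different genes, of which 386 were in the table, 3 of them under an older symbol. They cover prostaglandin synthesis, transport and receptors, cAMP and CREB target genes, immediate early genes, cytokines, chemokines and NF-kB targets, interferon-stimulated genes, fibrillar matrix and cross-linking, matrix proteases and inhibitors, hyaluronan metabolism, contractile and myofibroblast genes, TGF-beta and YAP target genes, steroid receptors and steroid metabolism, cell cycle, circadian clock, cholesterol synthesis and uptake, growth factors and ligands and unfolded protein and amino acid stress, with fibroblast, smooth muscle, epithelial, endothelial and immune cell markers and mitochondrially encoded genes. The design, the rule, the lists and the alternatives were chosen before the data were examined, except where a passage says otherwise. Of the list entries, 46 were not tested, for lack of counts or of a match in the table. Some genes stand in more than 1 list, among them 4 of the 7 smooth muscle markers and 4 of the 18 contractile genes tested. Calls of such lists are therefore not separate findings.

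Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, with an estimated correlation and fry beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Where the libraries of a group held 1 to 3 counts of a gene together, a ratio with its 95% binomial counting interval (Clopper-Pearson) replaces the log2 fold change. Where they held 0, the ratio is a lower bound against a floor of 3 counts over the group. These intervals and bounds cover counting error only.

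Totals ran from 16619898 to 25689584 counts per library. The biological coefficient of variation was 6.39%. Simulated data had the depths and dispersions found here, with 50 genes changed at each size. Each simulated gene had the same dispersion in all 4 groups, while the spread in the data was unequal between groups. The shares recovered and falsely called can therefore differ in the data. The fit recovered 30% of 1.25-fold, 80.0% of 1.5-fold, 92.0% of 2-fold and 98.0% of 4-fold changes at 1 h, and 42.0%, 70.0%, 92.0% and 94.0% at 24 h. With so few changed genes the adjustment was stricter than in the data, so these shares can be too low for it. Of the calls made there, 8.54% and 9.70% were false, and 0 of 20 lists without an effect were called. The simulation took depths and dispersions from the data, and not the correlation between the members of a list. It therefore cannot show how often camera, at the preset correlation, falsely calls lists with correlated members. The alternatives were DESeq2 size factors, library totals without TMM, DESeq2 1.42.0, limma-voom, non-robust dispersions, other filters on low counts, a fit to the 4 libraries compared, the replicate number as a block, minimum fold changes and leaving out each library in turn. Thinning every library to the smallest total and a correction for GC content and transcript length were added after the data were seen.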

Results

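Transcript counts were obtained for cervical stromal cells exposed to PGE2, a lipid mediator given clinically to ripen the cervix, or to DMSO as vehicle. Exposure lasted 1 h or 24 h, with 2 libraries in each group. At 1 h, replicates 1 and 2 held 19689426 and 23954611 counts with DMSO and 21544678 and 25059593 with PGE2. At 24 h they held 21568624 and 25689584 with DMSO and 21757386 and 16619898 with PGE2. Mitochondrially encoded genes took 1.34% to 2.47% of the counts of a library. In a principal component analysis the PGE2 24 h libraries lay apart from the other 6 on the first component, with 63.9% of the variance. The PGE2 1 h libraries lay apart on the second, with 22.4%.

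The first comparison asks which genes had responded to PGE2 after 1 h. Genes that cAMP signalling is known to induce were among those with the largest increases. SIK1, which encodes a salt-inducible kinase, went from 3.18 ± 0.495 to 558 ± 34.8 CPM (SD, n = 2), a log2 fold change of 7.46 ± 0.11. The orphan nuclear receptor genes NR4A3 and NR4A2 rose by 7.44 ± 0.12 and 6.26 ± 0.09. SERTM1 (6.77 ± 0.20), ZNF331 (6.52 ± 0.11), CRISPLD2 (5.68 ± 0.11) and SLCO4A1 (5.39 ± 0.16) rose too, as did ACKR3 (5.34 ± 0.25), which encodes a scavenging chemokine receptor. The peptide hormone gene SST (somatostatin) had 1 to 3 counts in DMSO and a PGE2 to DMSO ratio of 157 (27.9 to 6256). CGA, the common alpha subunit of the glycoprotein hormones, was as rare in DMSO and had a ratio of 68.4 (11.9 to 2739).

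Among the genes that fell at 1 h, CYR61, which encodes a matricellular protein, went from 504 ± 14.0 to 33.5 ± 1.38 CPM (SD, n = 2), or by -3.91 ± 0.07. The genes of the vasoconstrictor endothelin 1 (EDN1, -3.87 ± 0.21), connective tissue growth factor (CTGF, -2.56 ± 0.07) and adrenomedullin (ADM, -1.94 ± 0.10) fell. So did the G protein signalling regulator RGS4 (-2.47 ± 0.09), the ERK phosphatase DUSP6 (-2.39 ± 0.09) and C10orf10 (-3.28 ± 0.08). The zinc finger factors EGR2 (-2.23 ± 0.09) and EGR1 (-1.93 ± 0.10) were lower as well. In all, 1236 of 13073 genes changed, 859 upwards and 377 downwards, and 312 and 42 of these changed at least 2-fold.

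Of the genes that make, carry or sense prostaglandins, 3 of 16 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.721). The list's test pointed up, with a mean of -0.01 and a median of 0.01. PTGER4, the gene of the EP4 receptor, fell (-2.42 ± 0.17). The EP2 receptor gene PTGER2 (0.74 ± 0.08), the cyclooxygenase gene PTGS2 (0.72 ± 0.09) and the PGE synthase gene PTGES (1.59 ± 0.13) rose. PTGER3 (0.24 ± 0.14, adjusted p = 0.373) and HPGD (-0.39 ± 0.16, adjusted p = 0.164), which encodes a prostaglandin-degrading enzyme, did not pass the test. PTGER1 had 4 to 13 counts per library and was not tested.

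Of the cAMP and CREB target genes, 20 of 24 rose and 1 fell (21 and 1 adjusted over the list alone). The cAMP list had camera adjusted p = 2.17e-252, and adjusted p = 1.82e-04 with an estimated correlation. Their median log2 fold change was 2.95. CITED2, a transcriptional co-regulator, was the gene that fell. Like other members named without a value beside small counts, it lies outside the naming rule and was chosen after its values were seen. Of the immediate early genes, 13 of 21 rose and 4 fell (15 and 4 adjusted over the list alone). The immediate early list had camera adjusted p = 3.86e-13, and adjusted p = 0.0806 with an estimated correlation. FOSB (2.78 ± 0.09), KLF4 (2.86 ± 0.10) and BTG2 (1.95 ± 0.08) rose, and JUN, EGR1, EGR2 and KLF6 fell. Of the growth factors and ligands, 12 of 21 rose and 1 fell (12 and 4 adjusted over the list alone). The growth factor list had camera adjusted p = 2.43e-09, and adjusted p = 0.0806 with an estimated correlation. PDGFA (3.04 ± 0.20), EREG (2.52 ± 0.15), VEGFA (2.49 ± 0.08) and GDF15 (1.97 ± 0.13) rose, and BMP4 fell.

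Of the cytokines, chemokines and NF-kB targets at 1 h, 6 of 17 rose and 2 fell (6 and 6 adjusted over the list alone). The cytokine list had camera adjusted p = 3.15e-16, and adjusted p = 0.0558 with an estimated correlation. Its test pointed up and its mean was 0.99, but its median was -0.02. The cytokine genes LIF (4.21 ± 0.10) and IL6 (4.12 ± 0.15) rose, as did TNFAIP3 (3.42 ± 0.09) and NFKBIA (2.53 ± 0.09), which encode inhibitors of NF-kB signalling. CXCL1 and CCL2 fell. Of the interferon-stimulated genes, 1 of 14 rose and 7 fell (1 and 11 adjusted over the list alone). The interferon list had camera adjusted p = 3.33e-05, and adjusted p = 0.0653 with an estimated correlation. IFIT3 (-1.11 ± 0.07), IFIT2 (-0.94 ± 0.09), IFIT1 (-0.84 ± 0.12) and MX1 (-0.42 ± 0.08) were lower, and ISG15 was higher.

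Of the matrix proteases and inhibitors at 1 h, 9 of 24 rose and 4 fell (9 and 7 adjusted over the list alone). The protease list had camera adjusted p = 0.00357, and adjusted p = 0.0806 with an estimated correlation. Its test pointed up and its mean was 0.36, but its median was -0.06. The aggrecanase gene ADAMTS4 (5.22 ± 0.17), ADAMTS1 (2.46 ± 0.07) and the protease inhibitor gene TIMP3 (1.63 ± 0.07) rose. MMP1, MMP11 and MMP19 fell. Of the circadian clock genes, 4 of 17 rose and 1 fell (7 and 3 adjusted over the list alone). The clock list had camera adjusted p = 0.00235, and adjusted p = 0.0806 with an estimated correlation. PER1 (3.11 ± 0.11) and BHLHE40 (2.13 ± 0.07) rose, as did BHLHE41 and CRY2, and CIART, listed as C1orf51, fell. Of the genes of cholesterol synthesis and uptake, 5 of 17 rose and 0 fell (5 and 0 adjusted over the list alone). The cholesterol list had camera adjusted p = 0.0145, and adjusted p = 0.109 with an estimated correlation. INSIG1 (1.05 ± 0.07) and IDI1 (0.76 ± 0.09) rose, as did SC5D.

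The other lists had no camera call at 1 h. In the hyaluronan list, 3 of 15 rose and 0 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.145). The hyaluronan synthase gene HAS2 rose by 2.60 ± 0.10, and HAS1, with 0 counts in DMSO, was at least 17.5-fold higher. TNFAIP6 was the third. Of the TGF-beta and YAP targets, 8 of 17 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.394). That test pointed down, against a median of 0.25 and a mean of 0.02. AMOTL2 (-1.81 ± 0.08), SMAD7, CTGF and CYR61 fell, while INHBA rose (1.35 ± 0.06). Of the contractile genes, 1 of 18 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.145). TAGLN (-0.42 ± 0.07), ACTA2, ACTG2, TPM1 and TPM2 were lower and SMTN (0.43 ± 0.08) higher. In the fibrillar matrix list, 2 of 32 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.448). ELN and LOXL4 rose, and LOX (-0.39 ± 0.07) and TNC fell. In the stress list at 1 h, 4 of 17 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.293). DDIT4 (3.18 ± 0.11), HSPA5, HERPUD1 and DNAJB9 rose, and ATF4 and DDIT3 (-0.74 ± 0.08) fell. Of the steroid list, 2 of 16 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.495), these being STAR and TSC22D3. Of the cell cycle list, 1 of 27 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.180), AURKA (1.05 ± 0.18) up and MKI67 (-0.61 ± 0.11) down. Some calls named at 1 h were lost without 1 library. Without replicate 1 of DMSO at 1 h these were LOXL4, TNC, TNFAIP6, ACTG2 and TPM1 (adjusted p = 0.0556 to 0.158). Without its replicate 2 they were ELN, TNC, TNFAIP6, ACTG2, TPM1, STAR, TSC22D3, DNAJB9, KDR and MX1 (adjusted p = 0.0509 to 0.230). Without replicate 1 of PGE2 at 1 h they were ELN, ACTG2 and TSC22D3 (adjusted p = 0.0534 to 0.0953), and without its replicate 2 TNC, TNFAIP6, TPM1 and STAR (adjusted p = 0.0547 to 0.148). TPM1 was not called with the replicate number as a block either (adjusted p = 0.0565), nor ACTG2 with DESeq2 (adjusted p = 0.0924) or TNFAIP6 with library totals (adjusted p = 0.0588).

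Of the fibroblast markers at 1 h, 0 of 10 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.495). Of the smooth muscle markers, 0 of 7 rose and 2 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.150), namely SYNPO2 (-0.50 ± 0.06) and ACTG2, the latter not without either DMSO library or replicate 1 of PGE2 at 1 h (adjusted p = 0.0953 to 0.116). Of the epithelial markers, 0 of 5 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.837). Of the endothelial markers, 1 of 5 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.565), the gene being KDR, whose call was lost without replicate 2 of DMSO at 1 h (adjusted p = 0.0665). Of the immune cell markers, 1 of 3 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.421), the gene being FCER1G (2.02 ± 0.39). Of the mitochondrially encoded genes, 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.311). Without replicate 1 or replicate 2 of DMSO at 1 h, 762 or 710 genes changed. A correction for GC content and transcript length, added after the data were seen, gave 1013 increases and 1365 decreases against 859 and 377.

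**Figure D1:**
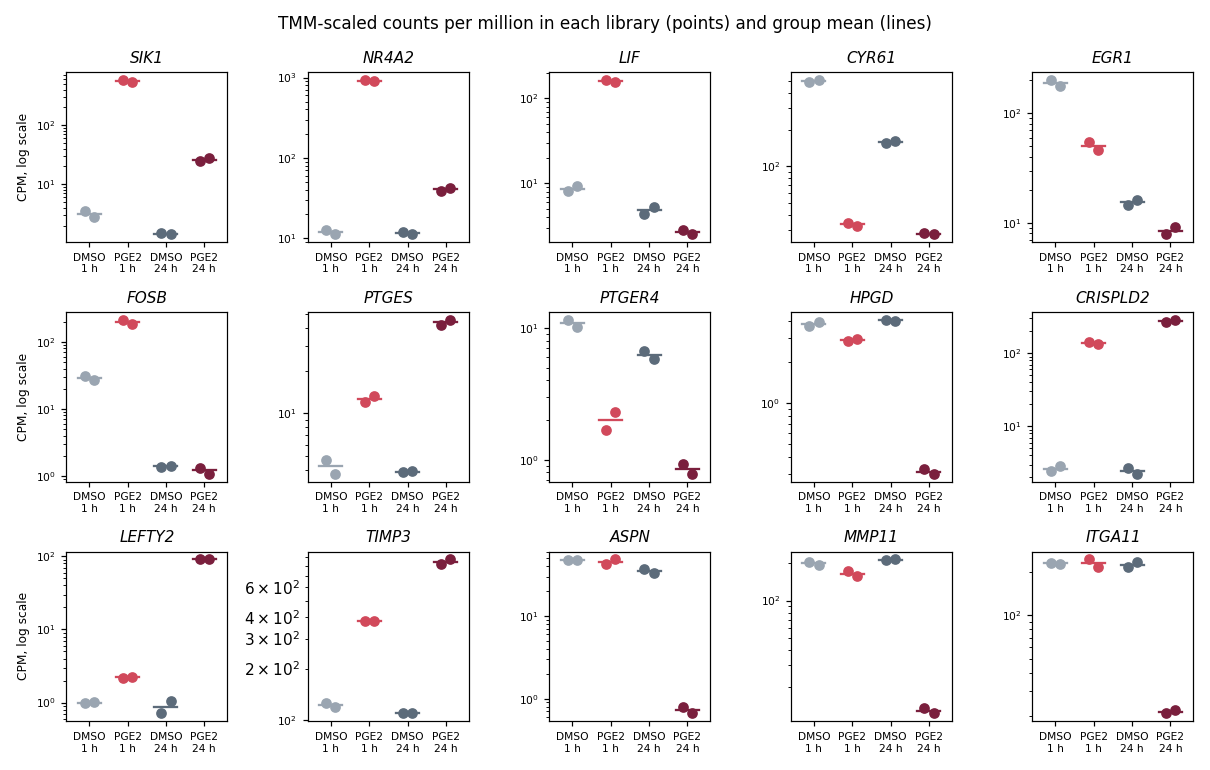
TMM-scaled CPM on a log axis for 15 genes, with a point per library and a line at the mean of the 2 libraries of each group. SIK1, NR4A2 and LIF are highest at 1 h of PGE2, and CRISPLD2, LEFTY2 and PTGES are highest at 24 h of PGE2.

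The second comparison asks what PGE2 had changed after 24 h. Genes of secreted hormones and binding proteins were among those with the largest increases. SST had 1 to 3 counts in DMSO and a PGE2 to DMSO ratio of 4015 (1111 to 33161), and the scavenger receptor gene SCARA5 a ratio of 1331 (368 to 10999). CGA and the insulin-like growth factor binding protein gene IGFBP1 had 0 counts in DMSO and were at least 169.9-fold and at least 144-fold higher. LEFTY2, an inhibitor of TGF-beta family signalling, went from 0.876 ± 0.238 to 91.3 ± 0.215 CPM (SD, n = 2), or by 6.68 ± 0.13. CRISPLD2 rose by 6.83 ± 0.11. SPINK13 (6.70 ± 0.26), SERTM1 (6.57 ± 0.24) and TNR (5.69 ± 0.24) rose too, as did CHGB (5.85 ± 0.18), the gene of chromogranin B.

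Genes with large decreases at 24 h included some with 1 to 3 counts left under PGE2. The PGE2 to DMSO ratio was 0.00434 (1.10e-04 to 0.0244) for the proton pump subunit gene ATP6V1C2 and 0.00783 (1.97e-04 to 0.0442) for the potassium channel subunit gene KCNMB2. It was 0.0175 (0.00210 to 0.0643) for the transcription factor gene ERG, 0.0254 (0.00517 to 0.0755) for TMC1 and 0.0295 (0.00600 to 0.0881) for the adaptor gene NEDD9. ASPN, which encodes the matrix proteoglycan asporin, fell from 35.4 ± 2.61 to 0.725 ± 0.0895 CPM (SD, n = 2), or by -5.58 ± 0.16. The neurotransmitter receptor genes CHRM4 (-5.48 ± 0.27) and GRIN2A (-4.41 ± 0.38) fell, as did EDN1 (-4.24 ± 0.32) and OMG (-4.23 ± 0.23). In all, 5779 genes (44.2% of those tested) changed, 2805 upwards and 2974 downwards, 619 and 843 of them at least 2-fold.

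Of the prostaglandin genes at 24 h, 4 of 16 rose and 10 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.463). HPGD (-3.66 ± 0.26), PTGER4 (-2.85 ± 0.22), PTGER3 (-1.23 ± 0.18), PTGS2 (-0.85 ± 0.14) and PTGER2 (-0.42 ± 0.08) were lower. PLA2G4A, which encodes a phospholipase that frees arachidonic acid, was lower too (-1.47 ± 0.12). PTGES rose by 3.48 ± 0.12, and PTGS1, PTGDS and PTGR1 rose with it. Of the cAMP and CREB targets, 16 of 24 rose and 1 fell (16 and 1 adjusted over the list alone). The cAMP list had camera adjusted p = 2.38e-33, and adjusted p = 0.0159 with an estimated correlation. Their median was 1.76. The phosphodiesterase genes PDE10A (4.93 ± 0.08) and PDE4B (3.26 ± 0.09) and the phosphatase gene DUSP1 (3.13 ± 0.09) rose, and CITED2 fell. Of the immediate early genes, 9 of 21 rose and 7 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.814). FOS (1.63 ± 0.18) and ZFP36 (1.21 ± 0.13) rose, and EGR2 (-3.69 ± 0.19) and EGR1 (-0.87 ± 0.13) fell.

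Cell cycle genes fell together at 24 h: 0 of 27 rose and 23 fell (0 and 23 adjusted over the list alone). The cell cycle list had camera adjusted p = 3.02e-07, and adjusted p = 0.0468 with an estimated correlation. Their median was -0.87. The proliferation marker MKI67 (-2.14 ± 0.13) and CENPF (-1.71 ± 0.09), TYMS (-1.57 ± 0.11) and RRM2 (-1.63 ± 0.12) were lower. Of the contractile and myofibroblast genes, 0 of 18 rose and 13 fell (0 and 13 adjusted over the list alone). The contractile list had camera adjusted p = 2.33e-10, and adjusted p = 0.20 with an estimated correlation. The collagen-binding integrin gene ITGA11 (-3.38 ± 0.09), the myosin light chain kinase gene MYLK (-1.91 ± 0.07), TAGLN (-1.82 ± 0.07) and TPM1 (-1.40 ± 0.06) were lower. Of the TGF-beta and YAP targets, 7 of 17 rose and 8 fell (7 and 8 adjusted over the list alone). The TGF-beta list had camera adjusted p = 0.0200, and adjusted p = 0.270 with an estimated correlation. CTGF (-3.79 ± 0.08), CYR61 (-2.49 ± 0.07) and LTBP2 (-1.54 ± 0.08) fell. That call was lost without replicate 1 (adjusted p = 0.0942) or replicate 2 (adjusted p = 0.0602) of PGE2 at 24 h.

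Of the genes of cholesterol synthesis and uptake at 24 h, 1 of 17 rose and 14 fell (1 and 14 adjusted over the list alone). The cholesterol list had camera adjusted p = 0.00324, and adjusted p = 0.121 with an estimated correlation. STARD4 (-0.84 ± 0.08), DHCR7 (-0.80 ± 0.08) and FDPS (-0.69 ± 0.07) were lower. Of the interferon-stimulated genes, 1 of 14 rose and 11 fell (1 and 11 adjusted over the list alone). The interferon list had camera adjusted p = 4.57e-07, and adjusted p = 0.0468 with an estimated correlation. IFIT1 (-1.98 ± 0.13), IFIT2 (-1.68 ± 0.10) and MX1 (-1.55 ± 0.09) were lower. Of the cytokines, chemokines and NF-kB targets, 10 of 17 rose and 4 fell (10 and 4 adjusted over the list alone). The cytokine list had camera adjusted p = 0.0117, and adjusted p = 0.270 with an estimated correlation. IL11 (2.98 ± 0.18), TNFAIP3 (1.89 ± 0.09) and CXCL12 (1.33 ± 0.07) rose, and IL33 (-2.40 ± 0.09), IL8, LIF and ICAM1 fell. Of the growth factors and ligands, 10 of 21 rose and 6 fell (10 and 7 adjusted over the list alone). The growth factor list had camera adjusted p = 0.00671, and adjusted p = 0.277 with an estimated correlation. The epidermal growth factor family gene EREG (4.78 ± 0.14), FGF10 (2.27 ± 0.09) and HGF (1.90 ± 0.08) rose. The BMP inhibitor gene GREM1 fell (-2.07 ± 0.08).

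In the fibrillar matrix list at 24 h, 8 of 32 rose and 17 fell (8 and 18 adjusted over the list alone, camera adjusted p = 0.0680). TNC (-2.64 ± 0.07) and POSTN (-1.53 ± 0.11) fell, as did the cross-linking enzyme gene LOXL4 (-1.88 ± 0.09), while the fibrillin gene FBN1 rose (1.41 ± 0.07). This list was called without replicate 1 of DMSO at 24 h (adjusted p = 0.0216). Of the proteases and inhibitors, 9 of 24 rose and 8 fell (9 and 9 adjusted over the list alone, camera adjusted p = 0.467). The test pointed up and the mean was 0.06, but the median was -0.18. MMP11 fell (-4.07 ± 0.08), and TIMP3 (2.95 ± 0.07), ADAMTS1 (2.95 ± 0.07) and ADAMTS5 (2.46 ± 0.08) rose. In the hyaluronan list, 4 of 15 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.814). TNFAIP6, whose product binds hyaluronan, rose (1.59 ± 0.09), as did UGDH, HAPLN1 and CEMIP, listed as KIAA1199. HAS2, TMEM2 (-0.73 ± 0.07) and HMMR (-1.38 ± 0.16) fell.

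In the steroid list at 24 h, 7 of 16 rose and 7 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.652). The test pointed up and the mean was 0.44, but the median was -0.21. The cholesterol carrier gene STAR (3.27 ± 0.22) and the cortisol-activating enzyme gene HSD11B1 (2.89 ± 0.16) rose. AKR1C1 was higher (1.18 ± 0.06) and AKR1C3 lower (-0.82 ± 0.08), but these genes and AKR1C2 are near copies, which leaves the assignment of their reads uncertain. In the circadian list, 7 of 17 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.652). PER1 (1.22 ± 0.13) and RORA (0.89 ± 0.07) rose, and BHLHE41 (-1.39 ± 0.09), NPAS2 and ARNTL fell. In the stress list, 4 of 17 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.0723). The serine and asparagine synthesis genes PSAT1 (-2.31 ± 0.09), PHGDH (-1.70 ± 0.08) and ASNS (-1.65 ± 0.09) fell, and VLDLR (1.12 ± 0.10), HSPA5, DNAJB9 and HMOX1 rose. This list was called without replicate 1 of DMSO at 24 h (adjusted p = 0.0335).

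Of the fibroblast markers at 24 h, 2 of 10 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.463). PDGFRA (1.02 ± 0.07) and PDGFRB rose, and VIM (-1.90 ± 0.10) and THY1 (-0.73 ± 0.09), FAP, DPT and LUM fell. Of the smooth muscle markers, 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0834), namely ACTG2 (-1.70 ± 0.13) and CNN1 (-1.39 ± 0.14) and PLN. Of the epithelial markers, 0 of 5 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0723), namely KRT18 (-2.10 ± 0.40), KRT19 (-1.95 ± 0.10) and KRT8 (-0.67 ± 0.16). Of the endothelial markers, 1 of 5 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.814), with KDR up and TEK (-0.47 ± 0.09) and TIE1 down. TIE1 was not called without either DMSO library of 1 h, replicate 2 of DMSO at 24 h or either PGE2 library of 24 h (adjusted p = 0.0530 to 0.212). Of the immune cell markers, 0 of 3 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.814). Of the mitochondrially encoded genes, 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.983), with a test that pointed up, a mean of -0.04 and a median of 0.02. Of the lists that camera called, the cAMP list kept its call with an estimated correlation at both times, and the cell cycle and interferon lists did at 24 h.

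**Figure D2:**
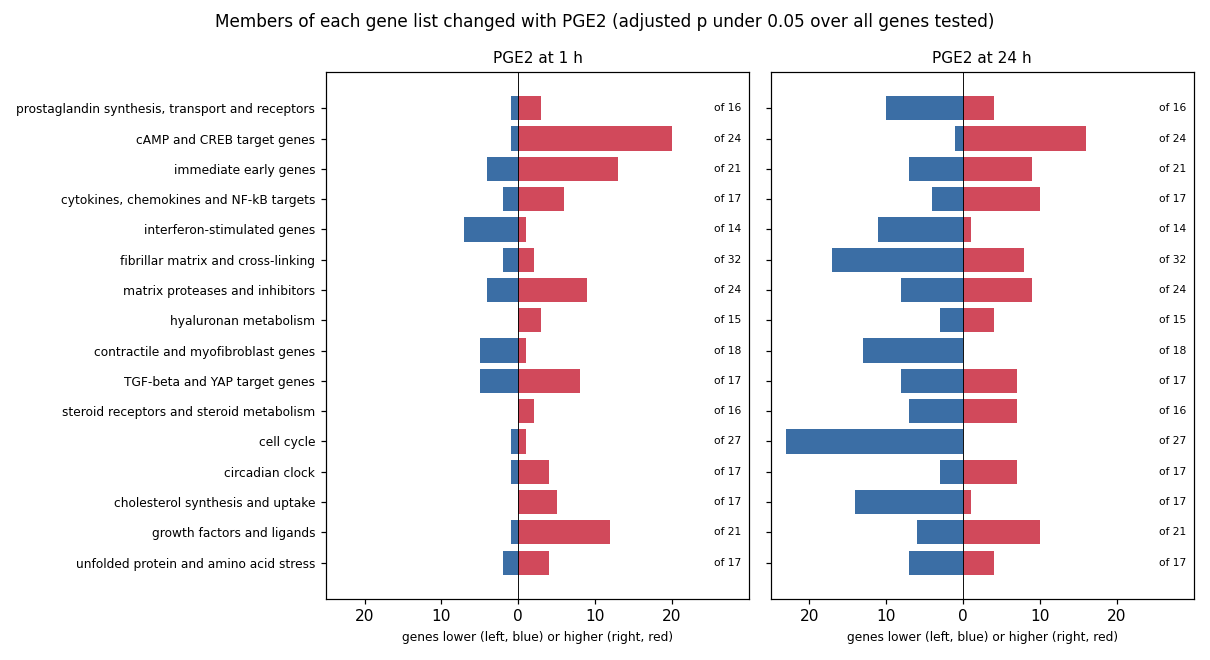
Number of members of 16 gene lists that were lower (to the left) or higher (to the right) with PGE2 than with DMSO at 1 h and at 24 h, with the number tested beside each name. At 24 h, 23 of 27 cell cycle genes were lower, and at 1 h, 20 of 24 cAMP and CREB targets were higher.

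The third comparison asks whether the PGE2 effect differed between the times. LEFTY2 (5.51 ± 0.33), F13A1 (5.17 ± 0.70) and SLC24A3 (5.04 ± 0.26) had some of the most positive differences (log2, 24 h minus 1 h). ZNF331 (-5.78 ± 0.14) and SOCS1 (-5.52 ± 0.44), which had risen at 1 h, and ASPN (-5.52 ± 0.20), which fell at 24 h alone, had some of the most negative. Fitted differences of 8.54 for SCARA5, 7.09 for IGFBP1, -6.97 for ATP6V1C2 and -6.50 for KCNMB2 depend on few counts in a group. That of IGFBP1 (adjusted p = 0.0488) was lost without replicate 2 of DMSO at 1 h (adjusted p = 1.00) or replicate 1 of PGE2 at 1 h (adjusted p = 0.0583). It was also lost without any single library of 24 h (adjusted p = 0.0699 to 0.0832). In all, the effects of 3879 genes differed, with that at 24 h above that at 1 h for 1642 and below it for 2237.

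For the cAMP and CREB targets, 6 of 24 were above 0 and 15 below (6 and 16 adjusted over the list alone). The cAMP list had camera adjusted p = 6.05e-13, and adjusted p = 0.0237 with an estimated correlation. Their median difference was -1.39. NR4A2 (-4.47 ± 0.12) and GEM (-2.58 ± 0.11) had smaller effects at 24 h, and PDE10A (2.31 ± 0.11) a larger one. For the immediate early genes, 4 of 21 were above 0 and 12 below (4 and 13 adjusted over the list alone). The immediate early list had camera adjusted p = 3.25e-04, and adjusted p = 0.356 with an estimated correlation. For the interferon-stimulated genes, 1 of 14 were above 0 and 9 below (1 and 9 adjusted over the list alone). The interferon list had camera adjusted p = 0.00765, and adjusted p = 0.177 with an estimated correlation. For the contractile genes, 1 of 18 were above 0 and 12 below (1 and 12 adjusted over the list alone). The contractile list had camera adjusted p = 1.06e-08, and adjusted p = 0.204 with an estimated correlation. For the cell cycle, 0 of 27 were above 0 and 18 below (0 and 20 adjusted over the list alone). The cell cycle list had camera adjusted p = 9.54e-06, and adjusted p = 0.0996 with an estimated correlation, and MKI67 differed by -1.53 ± 0.17.

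For the cholesterol genes, 0 of 17 were above 0 and 15 below (1 and 15 adjusted over the list alone). The cholesterol list had camera adjusted p = 8.61e-07, and adjusted p = 0.0512 with an estimated correlation, and INSIG1 differed by -1.49 ± 0.10. For the stress genes, 4 of 17 were above 0 and 8 below (4 and 8 adjusted over the list alone). The stress list had camera adjusted p = 0.00341, and adjusted p = 0.179 with an estimated correlation, and DDIT4 differed by -3.23 ± 0.15. For the TGF-beta and YAP targets, 4 of 17 were above 0 and 10 below (4 and 10 adjusted over the list alone). The TGF-beta list had camera adjusted p = 0.0475, and adjusted p = 0.264 with an estimated correlation. This call was lost without replicate 1 (adjusted p = 0.0501) or replicate 2 (adjusted p = 0.0969) of DMSO at 1 h or replicate 1 of PGE2 at 1 h (adjusted p = 0.0856). The other 14 lists had camera adjusted p from 0.0726 to 0.890. Across the lists, the cAMP call alone held with an estimated correlation.

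Of the genes tested, 514 were higher at both times, against 184.3 by chance, and the effect was larger at 24 h for 150 of them and smaller for 104. Another 177 were lower at both, against 85.8 by chance, and the decrease was larger at 24 h for 82 and smaller for 14. Opposite changes were rarer than chance gives, with 88 genes higher at 1 h and lower at 24 h (195.4 by chance) and 41 the reverse (80.9 by chance). Among genes called at 24 h and not at 1 h, the difference itself was called for 1258 of 2250 that rose and 1710 of 2709 that fell. Among those called at 1 h and not at 24 h, it was called for 175 of 257 that rose and 77 of 159 that fell. Across genes, which are not independent replicates, the effects at 1 h and 24 h had a Pearson correlation of 0.394 (0.177 without the filter on low counts) and a Spearman correlation of 0.259. With the GC and length correction, 3031 differences were positive and 2275 negative, against 1642 and 2237.

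The fourth comparison gives the vehicle background, DMSO at 24 h against DMSO at 1 h. Immediate early genes were lower at 24 h, led by FOSB (-4.36 ± 0.15), EGR3 (-3.81 ± 0.16), FOS (-3.52 ± 0.15) and EGR2 (-2.87 ± 0.10). EGR1 went from 190.0 ± 16.9 to 15.4 ± 1.2 CPM (SD, n = 2), or by -3.62 ± 0.11. CTGF (-2.38 ± 0.07), PTGS2 (-1.97 ± 0.11), CYR61 (-1.68 ± 0.06) and LIF (-0.84 ± 0.13) were lower too. DDIT4 (1.08 ± 0.11), AVIL (0.95 ± 0.11), C5orf54 (0.94 ± 0.13) and THAP2 (0.90 ± 0.13) were higher. GDPD3 was higher, a call lost without either DMSO library of 1 h or replicate 2 of DMSO at 24 h (adjusted p = 0.205 to 0.240). In all, 267 genes differed, 106 higher and 161 lower at 24 h, 1 and 29 of them at least 2-fold. Without replicate 1 of DMSO at 1 h their number was 92 (22 higher and 70 lower), without its replicate 2 it was 97 (16 and 81), and without replicate 1 of DMSO at 24 h it was 175 (52 and 123). Scaled by library totals alone, 152 genes were higher and 106 lower.

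Of the immediate early genes in DMSO, 0 of 21 were higher and 13 lower (1 and 15 adjusted over the list alone). The immediate early list had camera adjusted p = 2.00e-134, and adjusted p = 0.00297 with an estimated correlation. Of the cAMP and CREB targets, 1 of 24 were higher and 12 lower (2 and 12 adjusted over the list alone). The cAMP list had camera adjusted p = 1.51e-22, and adjusted p = 0.00565 with an estimated correlation. Of the TGF-beta and YAP targets, 0 of 17 were higher and 7 lower (0 and 9 adjusted over the list alone). The TGF-beta list had camera adjusted p = 1.08e-38, and adjusted p = 0.00297 with an estimated correlation. Of the cytokines, chemokines and NF-kB targets, 0 of 17 were higher and 5 lower (0 and 9 adjusted over the list alone). The cytokine list had camera adjusted p = 1.05e-10, and adjusted p = 0.0350 with an estimated correlation. Of the smooth muscle markers, 0 of 7 were higher and 2 lower (0 and 5 adjusted over the list alone). The smooth muscle list had camera adjusted p = 6.71e-06, and adjusted p = 0.0350 with an estimated correlation. The lower genes of that list were SYNPO2 and ACTG2, the latter not without any single library of DMSO or of PGE2 at 24 h (adjusted p = 0.0518 to 0.286).

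Of the contractile genes in DMSO, 0 of 18 were higher and 3 lower (0 and 7 adjusted over the list alone). The contractile list had camera adjusted p = 8.01e-07, and adjusted p = 0.156 with an estimated correlation. Of the growth factors and ligands, 0 of 21 were higher and 3 lower (0 and 4 adjusted over the list alone). The growth factor list had camera adjusted p = 8.89e-05, and adjusted p = 0.136 with an estimated correlation. Of the clock genes, 1 of 17 were higher and 2 lower (1 and 2 adjusted over the list alone). The clock list had camera adjusted p = 0.00481, and adjusted p = 0.0871 with an estimated correlation. Of the cell cycle genes, 1 of 27 were higher and 0 lower (2 and 0 adjusted over the list alone). The cell cycle list had camera adjusted p = 1.29e-04, and adjusted p = 0.0871 with an estimated correlation, pointing up. Of the proteases and inhibitors, 0 of 24 were higher and 4 lower (0 and 4 adjusted over the list alone). The protease list had camera adjusted p = 0.00147, and adjusted p = 0.0697 with an estimated correlation. Without replicate 1 of DMSO at 24 h it had adjusted p = 0.050 and was not called.

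Of the interferon-stimulated genes in DMSO, 0 of 14 were higher and 2 lower (0 and 2 adjusted over the list alone). The interferon list had camera adjusted p = 0.0251, and adjusted p = 0.136 with an estimated correlation. Without replicate 2 of DMSO at 24 h it was not called (adjusted p = 0.0885). Of the fibrillar matrix genes, 0 of 32 were higher and 1 lower (0 and 5 adjusted over the list alone). The fibrillar matrix list had camera adjusted p = 0.0230, and adjusted p = 0.424 with an estimated correlation. It was not called without replicate 1 of DMSO at 1 h (adjusted p = 0.0564) or of DMSO at 24 h (adjusted p = 0.130). The other 10 lists had camera adjusted p from 0.0505 to 0.960. The lowest was for mitochondrially encoded genes, which had a median of -0.40. With an estimated correlation, which was 0.962 for these genes, they had camera adjusted p = 0.638. At the preset correlation, far below that estimate, they were called without replicate 2 of DMSO at 1 h, either PGE2 library of 1 h or replicate 2 of DMSO at 24 h. Stress genes were called without replicate 1 of DMSO at 24 h (adjusted p = 0.0278) and fibroblast markers without its replicate 2 (adjusted p = 0.0438).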

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

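The genes and lists given with a difference in this part are those for which the PGE2 effect at 24 h minus that at 1 h (log2) passed the test of the difference itself. The paragraphs on the counts and on hormone and decidual genes rest on the effects at each time. Thinning and the GC and length correction were chosen after the counts were seen, the share of calls kept by the correction after its counts as well, and the neuroendocrine and decidual lists after the top genes were seen.

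PGE2 changed 5779 genes at 24 h and 1236 at 1 h, and the effects differed for 3879. With every library thinned to the smallest total, the 24 h count was 4.83 times that at 1 h. The smallest total was that of replicate 2 of PGE2 at 24 h. Thinning could therefore hardly lower this ratio and is a weak test of depth. After a correction for GC content and transcript length, 99.5% of the 24 h calls with both measures kept call and direction, which argues against these biases as the cause of those calls. The correction also raised the count at 1 h and brought the ratio to 2.82, between the bounds of 1.5 and 3 set in advance, so that how far these biases shape the ratio cannot be told apart from a wider response at 24 h. The test of the difference compares the 2 exposure times, each against its own DMSO. It cannot separate exposure time from anything else that differed between the 1 h and 24 h libraries, so the reason for the wider response stays open.

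SST, CGA, CHGB and IGFBP1 were among the genes with the largest increases at 24 h. Neuroendocrine cells that express CHGA, INSM1 or NEUROD1 are argued against, as these genes and INS had 0 counts in all 8 libraries. Of 16 listed markers, 7 had the counts to be tested, and 2 were higher (12.5% of those listed, 28.6% of those tested), where most were expected. SNAP25 (3.99 ± 0.16) and CPE (1.72 ± 0.10) were higher, and STMN2 (-1.23 ± 0.06) and ENO2 (-0.41 ± 0.10) lower. STMN2 had 5450 and 6677 raw counts with DMSO at 24 h, and ENO2 had 795 and 919. A few neuroendocrine cells could hardly raise such counts, so these 2 genes say little on the question. PCSK2, too rare to be tested, had 13 counts with PGE2 and 1 in DMSO at 24 h, a ratio of 16.5 (2.48 to 700.4), another rise. Of 19 genes linked to decidualization, the change of uterine stromal cells in pregnancy, 15 were tested, and 9 were higher (60% of those tested, 47.4% of those listed) and 4 lower, with a median of 0.63. Adjusted over these 2 lists, camera gave p = 0.0110 for the decidual list and 0.155 for the neuroendocrine one, and with an estimated correlation neither passed (0.0828 and 0.217). PRL, with 1 count in DMSO, had a ratio of 110.3 (19.3 to 4406), IL15 (1.22 ± 0.17), HAND2 (1.21 ± 0.11), SOD2 (1.07 ± 0.07) and FOXO1 (0.89 ± 0.06) were higher, and PRLR (-1.01 ± 0.09), WNT4, CRYAB and GPX3 were lower. The difference from the effect at 1 h did not pass for SST, CGA, PRL and FOXO1 (adjusted p = 0.0897 to 0.131). It was positive for IL15 (1.25 ± 0.27) and SOD2 (1.18 ± 0.10) and negative for HAND2 (-1.69 ± 0.15), which rose more at 1 h. CEBPB, also among the 9, had 737 and 823 raw counts with DMSO and 4156 and 4339 with PGE2 at 1 h. At 24 h it had 1361 and 1336 with DMSO and 1492 and 1464 with PGE2. The test set in advance asked for most of the decidual genes to be higher, which holds for those tested and not for those listed, so a decidual-type gene programme at 24 h stays an open hypothesis.

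Of the lists whose effects differed, the median difference was -1.39 for cAMP and CREB targets, -0.87 for immediate early genes, -0.79 for interferon-stimulated genes, -0.72 for the cell cycle, -0.63 for cholesterol synthesis and uptake, -0.53 for contractile genes, -0.49 for TGF-beta and YAP targets and -0.19 for the stress list. With an estimated correlation the cAMP list kept its call (adjusted p = 0.0237), and the other 7 lost it (adjusted p = 0.0512 to 0.356). The TGF-beta and YAP call was lost without replicate 1 (adjusted p = 0.0501) or replicate 2 (adjusted p = 0.0969) of DMSO at 1 h or replicate 1 of PGE2 at 1 h (adjusted p = 0.0856).

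For single genes that rose at 1 h, the differences with their standard errors were as follows. Higher at both times with the larger effect at 24 h were LEFTY2 (5.51 ± 0.33), IGFBP4 (2.80 ± 0.13), PDE10A (2.31 ± 0.11), EREG (2.25 ± 0.23), CHGB (2.05 ± 0.40) and PTGES (1.89 ± 0.19). So were ADAMTS5 (1.88 ± 0.11), STAR (1.88 ± 0.40), FGF10 (1.60 ± 0.12), HGF (1.53 ± 0.10), TIMP3 (1.32 ± 0.09) and TNFAIP6 (1.25 ± 0.13). So were PDE4B (1.21 ± 0.13), CRISPLD2 (1.15 ± 0.18), SNAP25 (1.09 ± 0.28), SOCS3 (0.94 ± 0.16) and ADAMTS1 (0.49 ± 0.09). Higher at both times with the smaller effect at 24 h were ZNF331 (-5.78 ± 0.14), NR4A3 (-5.01 ± 0.25), NR4A2 (-4.47 ± 0.12), ADAMTS4 (-3.97 ± 0.23), SIK1 (-3.32 ± 0.23) and IL6 (-3.05 ± 0.39). So were ACKR3 (-2.73 ± 0.79), TUBA4A (-2.59 ± 0.21), KLF4 (-2.42 ± 0.15), DUSP8 (-2.11 ± 0.61), PER1 (-1.89 ± 0.17) and DUSP1 (-1.76 ± 0.13). So were VEGFA (-1.75 ± 0.11), HAND2 (-1.69 ± 0.15), TNFAIP3 (-1.52 ± 0.13), NFKBIA (-1.27 ± 0.12), HOXA3 (-1.26 ± 0.20) and HOXA9 (-0.59 ± 0.17). Higher at 1 h and lower at 24 h were SOCS1 (-5.52 ± 0.44), LIF (-5.06 ± 0.18), GDF15 (-3.69 ± 0.21), HAS2 (-3.16 ± 0.17), LOXL4 (-2.27 ± 0.12) and BTG2 (-2.19 ± 0.11). So were BHLHE41 (-1.98 ± 0.12), INHBA (-1.72 ± 0.09), PTGS2 (-1.58 ± 0.17), INSIG1 (-1.49 ± 0.10), PRLR (-1.33 ± 0.12) and PTGER2 (-1.17 ± 0.11). So were IDI1 (-1.05 ± 0.12) and ENO2 (-0.74 ± 0.14). Called at 1 h alone, as higher, were SLCO4A1 (-4.71 ± 0.37), DDIT4 (-3.23 ± 0.15), FOSB (-2.97 ± 0.28), PDGFA (-2.83 ± 0.34), GEM (-2.58 ± 0.11) and BHLHE40 (-2.09 ± 0.10). So were AURKA (-1.06 ± 0.26), HOXA13 (-0.96 ± 0.10), THAP2 (-0.81 ± 0.18) and SMTN (-0.57 ± 0.11).

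Genes that fell at 1 h had these differences. Lower at both times, and more so at 24 h, were CHRM4 (-4.95 ± 0.34), MMP11 (-3.79 ± 0.11), TNC (-2.34 ± 0.09), MKI67 (-1.53 ± 0.17), EGR2 (-1.46 ± 0.24) and TAGLN (-1.40 ± 0.10). So were ACTG2 (-1.27 ± 0.17), CTGF (-1.23 ± 0.11), TPM1 (-1.15 ± 0.09), IFIT1 (-1.15 ± 0.18), MX1 (-1.13 ± 0.12) and RGS4 (-0.84 ± 0.16). So was IFIT2 (-0.74 ± 0.14). Lower at both times, and less so at 24 h, were DUSP6 (1.70 ± 0.13), CYR61 (1.42 ± 0.10), AMOTL2 (1.25 ± 0.11), EGR1 (1.06 ± 0.16), ADM (0.63 ± 0.15) and DDIT3 (0.43 ± 0.12). For CYR61 and EGR1 the smaller effect went with a lower level in DMSO, not with a return under PGE2. CYR61 had 494 and 514 CPM with DMSO at 1 h and 155 and 160 at 24 h. With PGE2 it had 34.5 and 32.5, then 28.3 and 27.8. EGR1 had 54.1 and 45.9 CPM with PGE2 at 1 h and 7.88 and 9.14 at 24 h. Lower at 1 h and higher at 24 h was C10orf10 (3.47 ± 0.10). Called at 1 h alone, as lower, were C5orf54 (0.70 ± 0.20) and SYNPO2 (0.36 ± 0.09). The 1 h calls of LOXL4, TNC, TNFAIP6, ACTG2, TPM1, STAR and MX1, on which their place in these groups rests, were lost without 1 or more of the 1 h libraries. The 1 h calls of genes that the naming rule did not take at 1 h, such as ENO2, PRLR and HOXA13, were not followed through these fits.

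The rest had not passed the test at 1 h. Called at 24 h alone, as higher, were F13A1 (5.17 ± 0.70), SLC24A3 (5.04 ± 0.26), TNR (4.81 ± 0.95), HSD11B1 (2.46 ± 0.26), CPE (1.75 ± 0.14) and FBN1 (1.41 ± 0.09). So were CXCL12 (1.35 ± 0.09), IL15 (1.25 ± 0.27), PDGFRA (1.2 ± 0.10), SOD2 (1.18 ± 0.10), AKR1C1 (1.07 ± 0.09) and VLDLR (0.94 ± 0.14). So were ZFP36 (0.89 ± 0.18), IGFBP5 (0.82 ± 0.12), AVIL (0.77 ± 0.15), RORA (0.71 ± 0.10), IGFBP6 (0.57 ± 0.15) and IGFBP3 (0.49 ± 0.12). So was IGFBP2 (0.40 ± 0.13). Called at 24 h alone, as lower, were ASPN (-5.52 ± 0.20), GRIN2A (-4.31 ± 0.44), OMG (-4.21 ± 0.27), ITGA11 (-3.39 ± 0.11), HPGD (-3.26 ± 0.33) and IL33 (-2.15 ± 0.12). So were PSAT1 (-2.12 ± 0.12), KRT18 (-2.08 ± 0.52), KRT19 (-1.95 ± 0.14), GREM1 (-1.88 ± 0.11), MYLK (-1.83 ± 0.09) and VIM (-1.80 ± 0.14). So were TYMS (-1.69 ± 0.15), ASNS (-1.63 ± 0.12), PHGDH (-1.57 ± 0.11), CENPF (-1.48 ± 0.12), PTGER3 (-1.47 ± 0.23) and LTBP2 (-1.40 ± 0.11). So were RRM2 (-1.38 ± 0.16), POSTN (-1.36 ± 0.14), PLA2G4A (-1.35 ± 0.17), EGR3 (-1.24 ± 0.32), KRT34 (-1.17 ± 0.20) and CNN1 (-1.14 ± 0.18). So were STMN2 (-1.10 ± 0.09), STARD4 (-0.97 ± 0.11), HMMR (-0.90 ± 0.23), AKR1C3 (-0.82 ± 0.10), DHCR7 (-0.78 ± 0.12) and TMEM2 (-0.74 ± 0.10). So were THY1 (-0.65 ± 0.13), FDPS (-0.59 ± 0.10) and TEK (-0.51 ± 0.12). The difference for KRT18 did not pass without replicate 1 of PGE2 at 24 h (adjusted p = 0.0676).

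The fitted differences of SCARA5 (8.54 ± 1.33), IGFBP1 (7.09 ± 2.52), ATP6V1C2 (-6.97 ± 0.50), KCNMB2 (-6.50 ± 0.59), DUSP2 (-5.76 ± 1.34), ERG (-5.22 ± 0.54), TMC1 (-4.66 ± 0.61) and NEDD9 (-3.53 ± 0.51) rest on groups with few counts and change with the prior count. That of IGFBP1 (adjusted p = 0.0488) did not pass without replicate 2 of DMSO at 1 h (4.75, adjusted p = 1.00), replicate 1 of PGE2 at 1 h (adjusted p = 0.0583) or any 1 of the 24 h libraries (adjusted p = 0.0699 to 0.0832).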

How the results depend on the processing

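Among lists and genes named by the rule, none that passed the threshold reversed its direction under the alternatives run, but the majority among changed genes did turn. Genes named outside the rule were not followed through the alternatives. With the GC and length correction, 1013 rose and 1365 fell at 1 h (859 and 377 as reported), 3527 and 3178 at 24 h (2805 and 2974), and 3031 differences were positive and 2275 negative (1642 and 2237). With library totals, 152 genes were higher and 106 lower in DMSO at 24 h (106 and 161). The median log2 fold change of all genes tested moved in the same directions. With the GC and length correction it went from -0.0035 to -0.0520 at 1 h, from -0.0079 to 0.0174 at 24 h and from -0.0102 to 0.0586 for the difference. With library totals it went from 0.0046 to 0.0576 in DMSO. Counts of changed genes not given here stayed within 1.5 times the value reported. The GC and length correction and the thinning were chosen after seeing the data. Changed genes at 1 h (1236) became 2378 with the GC and length correction, 2004 with the replicate number as a block within each time, 354 at a fold of at least 2 and 633 against a 1.2-fold change (glmTreat), and leaving out 1 library gave 710 to 1346. At 24 h (5779) the fold minimum gave 1462 and glmTreat 3313, and for the difference between the times (3879) they gave 1272 and 2392. The DMSO count (267) became 428 without a filter on low counts, 415 with the 4 DMSO libraries alone, 648 with the GC and length correction, 168 with the replicate block, 30 at a fold of at least 2, 78 with glmTreat and 92 to 353 with 1 library left out. Fold minimums are stricter by construction, and for the other settings the cause was not tested. The correlation of the effects (0.394) was 0.177 without the filter and 0.342 to 0.378 with 1 library left out.

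Of the 22 lists, camera with an estimated correlation called 1 at 1 h (8 with the preset one), 3 at 24 h (8), 1 for the difference (8) and 5 for DMSO (12). By fry, which does not compare a list with other genes, 14, 16 and 17 lists moved at 1 h, at 24 h and for the difference. Leaving out 1 library gave 7 to 10 called lists at 24 h. Single named genes kept their side of the threshold, and their direction if past it, in 1950 of the gene and setting pairs at 1 h, with 26 no longer past it and 17 newly past it. At 24 h the counts were 2154, 10 and 7, for the difference 1818, 11 and 7, and for DMSO 1551, 74 and 25. Calls of named genes lost other than by leaving out a library were, besides those given at 1 h, TIE1 at 24 h under 5 alternatives (adjusted p = 0.0506 to 0.207) and, for the difference, IGFBP1 under 3 (adjusted p = 0.0508 to 0.0618). The TGF-beta and YAP list lost its call for the difference with the replicate block too (adjusted p = 0.0585). In DMSO the genes included GDPD3 under 2 (adjusted p = 0.0581 to 0.0633) and ACTG2 under 3 (adjusted p = 0.0683 to 0.121). A library left alone in its group was assumed to vary like the other groups. The labels do not say what a replicate number stands for, and 2 pairs per comparison are fewer than the 3 needed to test it, with correlations of 0.143, 0.115 and -0.0668 between the deviations of the groups compared. With the replicate number as a block, 992 genes passed at 1 h, 5214 at 24 h and 3326 for the difference, and within each time 6642 at 24 h and 4982 for the difference. Thinned to the smallest total, the libraries gave 1140 changed genes at 1 h and 5509 at 24 h, of which 1068 and 5338 were the genes called at full depth. In the simulation, 1.25-fold changes were recovered for 30% of 50 genes at 1 h and 42.0% of 50 at 24 h. Far fewer genes changed there than in the data, which made the adjustment stricter. How often small changes are missed in the data is therefore not known from it.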

Other observations

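The 12 gene families tested here were chosen after the tables were seen and adjusted within each time, and the tests on the vehicle genes were chosen after their result was seen. At 1 h, of the dual specificity phosphatase genes, 6 of 18 rose and 2 fell (camera adjusted p = 1.10e-05, adjusted p = 0.0725 with an estimated correlation). DUSP1 (4.89 ± 0.10), DUSP2 (4.29 ± 0.31), DUSP8 (3.95 ± 0.26) and DUSP4 (1.88 ± 0.10) rose, while DUSP6 and DUSP7 (-0.55 ± 0.16) fell. Of the suppressors of cytokine signalling, 5 of 8 rose and 1 fell (camera adjusted p = 0.00750, adjusted p = 0.475 with an estimated correlation), with SOCS1 at 3.62 at 1 h and -1.91 at 24 h and SOCS3 higher at both times (1.34 and 2.28). HOX genes counted 6 of 17 rose and 1 fell (camera adjusted p = 0.00750, adjusted p = 0.577 with an estimated correlation), among them HOXA3 (2.04 ± 0.14), HOXA9 (1.13 ± 0.12) and HOXA13 (0.81 ± 0.07), and tubulin genes 4 of 10 rose and 0 fell (camera adjusted p = 0.00750, adjusted p = 0.688 with an estimated correlation), led by TUBA4A (3.21 ± 0.14).

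At 24 h, of the insulin-like growth factor binding proteins, 6 of 7 rose and 0 fell (camera adjusted p = 2.65e-06, adjusted p = 0.0713 with an estimated correlation). IGFBP4 (3.15 ± 0.09), IGFBP5 (1.01 ± 0.09), IGFBP3 (0.63 ± 0.08), IGFBP6 (0.62 ± 0.11) and IGFBP2 (0.49 ± 0.09) rose beside IGFBP1, and IGFBP7 was at -0.12 ± 0.08 and not called. Of the cytosolic ribosomal protein genes, 0 of 82 rose and 35 fell (camera adjusted p = 0.0139, adjusted p = 0.805 with an estimated correlation), with a median of -0.29 that was -0.33 when scaled by library totals. Of the keratins, 0 of 5 rose and 4 fell (camera adjusted p = 0.0133, adjusted p = 0.569 with an estimated correlation), KRT34 (-1.49 ± 0.16) beside the 3 epithelial markers. The other 8 families at 1 h and 9 at 24 h were not called, with camera adjusted p from 0.214 to 0.624 and from 0.237 to 0.909.

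Of the 377 genes lower with PGE2 at 1 h, 50 (13.3%) were also lower in DMSO at 24 h than at 1 h, against 4.64 by chance (odds ratio 17.3), CYR61, CTGF, EGR1 and EGR2 among them. The other overlaps were above chance too: 55 genes were higher with PGE2 and lower in DMSO at 24 h (10.6 by chance, odds ratio 7.81), 34 higher in both (6.97 by chance) and 10 lower with PGE2 and higher in DMSO at 24 h (3.06 by chance). These chance values take the lists as independent, while the comparisons share the DMSO 1 h libraries. With a different one of these in each comparison, 25 genes were lower in both in each of the 2 assignments, with an odds ratio of 38.6 (22.5 to 64.9) in the lower case, which argues against noise of single libraries and leaves open something common to both DMSO 1 h libraries. The other overlaps then held 3 to 34 genes, with odds ratios of 7.22 (1.69 to 23.9) to 25.4 (5.91 to 84.8). PGE2 did not lower all of the genes that were higher in DMSO at 1 h than at 24 h. Of these 161 genes, 55 were higher with PGE2 and 50 lower, so that 52.4% of those called rose, FOS (1.97 ± 0.09) and FOSB among them. Of all genes changed by PGE2 at 1 h, 69.5% rose. The bound for this test was set with the counts known, so its outcome weighs neither for nor against a general lowering. No library precedes 1 h, so whether these genes were transiently high in the vehicle is not known. What links the comparisons stays open.

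Exons shared with another gene can add that gene's reads to a count, and the strand setting is not stated. Of 158 genes whose values are given and that were found in the annotation, 20 share at least 10% of their exon bases with another gene: ASNS (79.7%), TYMS (58.2% with ENOSF1), DDIT4 (48.5% with DDIT4-AS1), DUSP6 (39.4%), KCNMB2 (36.2%), VIM (34.3% with VIM-AS1), SPINK13 (31.6%), ATP6V1C2 (31.1% with PDIA6), FDPS (28.9% with RUSC1-AS1), RRM2 (27.9%), IL6 (25%), TPM1 (23.5% with TPM1-AS), TUBA4A (23.4% with STK16), PDGFRA (19.5%), HOXA9 (19.3%), TAGLN (18.4% with PCSK7), THAP2 (15.2% with ZFC3H1), IGFBP7 (14.9% with POLR2B), THY1 (14%) and SLCO4A1 (12.5% with SLCO4A1-AS1).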
